A study of Mus musculus with 9 samples.

How the data were processed

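RNA of 3 tissues of the pregnant mouse uterus at day 6.5 post-coitum was measured on 9 one-colour Agilent whole mouse genome arrays labelled with Cy3, 3 arrays per tissue, per the labels' protocols. The tissues were surrounding decidua from the implantation site, inter-implantation decidua, which is the uterine segment between sites, and extra-embryonic tissue. The dissected uterine segments also held muscle, stroma and epithelium, and the tissue tag of the extra-embryonic samples names the ectoplacental cone, per the labels. The females were B6CBA F1/J and the males CD1. The labels give 3 mice and also say that the samples were run in duplicate, and they give different RNA extraction kits and RNA quality limits in different fields, so which of these applied to a given array is not known.

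The deposited values are log2 spot intensities, as read from the values: they ran from 4.94 to 16.0, and the top lies at the log2 of the largest 16-bit scanner reading. The array medians lay at 6.29 to 6.30 and the 75th percentiles at 8.94 to 8.95, so all 9 arrays lay on nearly one distribution as deposited. The scanner software, background correction and normalization method are not given in the sources used here. A shift in total RNA between tissues cannot be seen in values scaled in this way, and values near 16 are compressed by the scanner limit. No detection flags were used here. Without scanner files, a gene was treated as dim in a tissue when all 3 arrays lay below their array medians. It then has only an upper bound there, and the ratio is written as "at least", with each sample's higher value of its own and the array median taken for the dim tissue. A gene within 0.1 log2 units of 16 on all arrays of a tissue was treated as saturated there, which also gives only a bound. The ratio of a called gene that met either limit in only some arrays or samples of a tissue is also written as "at least". The number of arrays, not a count of molecules, limits the precision.

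Of 45220 features, 33026 were paired with 1 gene in the platform annotation, 0 with several, and 12194 were unnamed here. Symbols were updated through the gene number for 32438 features and through the accession for 36, with a gene table of assembly GRCm38.p6, and 552 kept the annotation's name. No coordinates were used, since the build behind the array design is not given in the sources used here. The log2 values of a gene's features were averaged, which gave 22479 genes, 16339 of them with 1 feature. Between 307 pairs of features of one gene with a range of at least 3 log2 units, the median correlation over the arrays was 0.983, against 0.005 for 2000 random pairs. In tests per feature, 1 gene had features called in opposite directions between extra-embryonic tissue and surrounding decidua, and 0 had in the other comparisons.

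Arrays of one tissue were compared before averaging. Extra-embryonic replicates 1 and 2 differed with an SD of 0.08 log2 units per array, and inter-implantation replicates 2 and 3 with an SD of 0.10, over features above a level of 8. The spread of repeated features of one gene within an array was 0.17 to 0.23, from 161 to 178 genes with at least 10 features. Other pairs of one tissue differed with SDs of 0.22 to 0.67. The lowest, 0.23 and 0.22, were those of extra-embryonic replicate 3 with replicates 1 and 2, and lay within that spread. Of their features 5.48% and 4.9% lay over 1 log2 unit apart, against 0.581% and 1.35% in the pairs at 0.08 and 0.10. Only these last, near-identical pairs lay below the spread. Each of them was therefore averaged and counted as 1 sample, which left 7 samples: 3 of surrounding decidua, 2 of inter-implantation decidua and 2 of extra-embryonic tissue. This was decided after the data were examined. The design fixed beforehand took all 9 arrays as separate samples, and its counts are given beside those of the 7 samples. The titles number the mice from 1 to 3 in each tissue, so the same number was taken as the same mouse, and the mouse number was also fitted as a block over all 9 arrays. Deviations of same-numbered samples from their group means correlated at -0.09 to 0.11 between surrounding and inter-implantation decidua, -0.38 to 0.05 between extra-embryonic tissue and surrounding decidua and -0.11 to 0.08 between extra-embryonic tissue and inter-implantation decidua, over 8190 genes, so the values themselves do not show the pairing. Differently numbered samples of extra-embryonic tissue and surrounding decidua correlated at -0.32 to 0.40. The highest was extra-embryonic replicate 3 with surrounding decidua replicate 2. Deviations from one group mean are tied to each other, so these values are not independent.

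Linear models were fitted to all 3 tissues with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, tissue as the sole term), which leaves 4 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and a difference of at least 2-fold. All adjusted p-values of genes come from this test. On simulated data with 22479 genes, log2 changes of 2, 3 and 4 were called in the right direction for 53.7%, 79.1% and 92.4% of changed genes for surrounding decidua minus inter-implantation decidua. The shares were 55.2%, 74.6% and 89.4% for extra-embryonic tissue minus surrounding decidua, and 47.8%, 76.1% and 87.9% for extra-embryonic tissue minus inter-implantation decidua. Among the unchanged genes 6, 10 and 7 were called in these comparisons. The simulated noise was independent, with 1 spread per gene in all samples, and the changed genes had middle mean levels. Real spreads differed between tissues, so these shares may be too high. Pcp4 had an SD of 2.76 in inter-implantation decidua against 0.65 in surrounding decidua. Cnn1 and Pcp4 differed by -7.95 and -6.33 log2 units between these tissues and were not called.

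Before the data were examined, 35 gene lists with 568 members were written from general knowledge of the uterus, decidua, trophoblast and early embryo, and 535 members were measured. Some genes stand in more than 1 list. Each list was tested with limma's camera at its preset correlation of 0.01, adjusted over 105 tests, and the alternatives were camera with an estimated correlation and fry. With an estimated correlation camera takes its p-values on the 4 residual degrees of freedom. A low adjusted p over 105 tests is then hard to reach whatever the correlation. List members called are counted over all genes and adjusted over the list alone. Means ± SD are over samples, and SE is the standard error of a log2 difference.

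Named genes follow a rule fixed beforehand. Per comparison it takes, among called genes with an official symbol and with no overlap between the tissues' arrays, the 6 with the largest rise and the 6 with the largest fall. It adds up to 2 called members per direction of each list described, and check genes whatever their result: Prl8a2, Bmp2, Wnt4, Hand2, Tpbpa, Ascl2, Hand1, Elf5, Acta2, Myh11, Cdh1, Pecam1, Flt1, Ncr1, Vegfa, Igf2 and H19. Prl3d1, also a check gene, was not analysed here. For genes higher in 1 tissue than in both others it takes the 5 with the largest smaller difference. These choices use measured differences, so they do not rank genes that have only a bound. The first part was also applied to the fit of all 9 arrays. Alternatives covered normalization, a filter on dim genes, the rule for several features, the replicate block, the samples in the fit, variance options, array weights, thresholds and leaving out each sample. Figures were drawn with matplotlib 3.10.9 from tables made with pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15.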

Results

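Gene expression was measured on 9 arrays from 3 tissues of the mouse uterus at day 6.5 post-coitum, when the embryo has implanted and the uterine stroma around it has turned into decidua. Surrounding decidua came from the implantation site after the embryonic part had been removed, inter-implantation decidua from the uterine wall between sites, and extra-embryonic tissue from the embryonic side of the site. Values are deposited log2 signals of 22479 genes. As deposited, all 9 arrays lay on nearly one distribution, with medians of 6.29 to 6.30, so a difference in overall brightness cannot be seen.

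The arrays grouped by tissue only in part. Extra-embryonic replicates 1 and 2 correlated at r = 0.995 over all features and inter-implantation replicates 2 and 3 at r = 0.993. Each of these pairs differed by less than the spread of repeated features within an array and was counted as 1 sample. Inter-implantation replicate 1 correlated at 0.937 and 0.933 with the other inter-implantation arrays, and at 0.950, 0.927 and 0.960 with surrounding decidua replicates 1, 2 and 3. Within surrounding decidua, r was 0.953 to 0.976. These correlations are across features of single arrays, and features are not independent replicates.

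**Figure D1:**
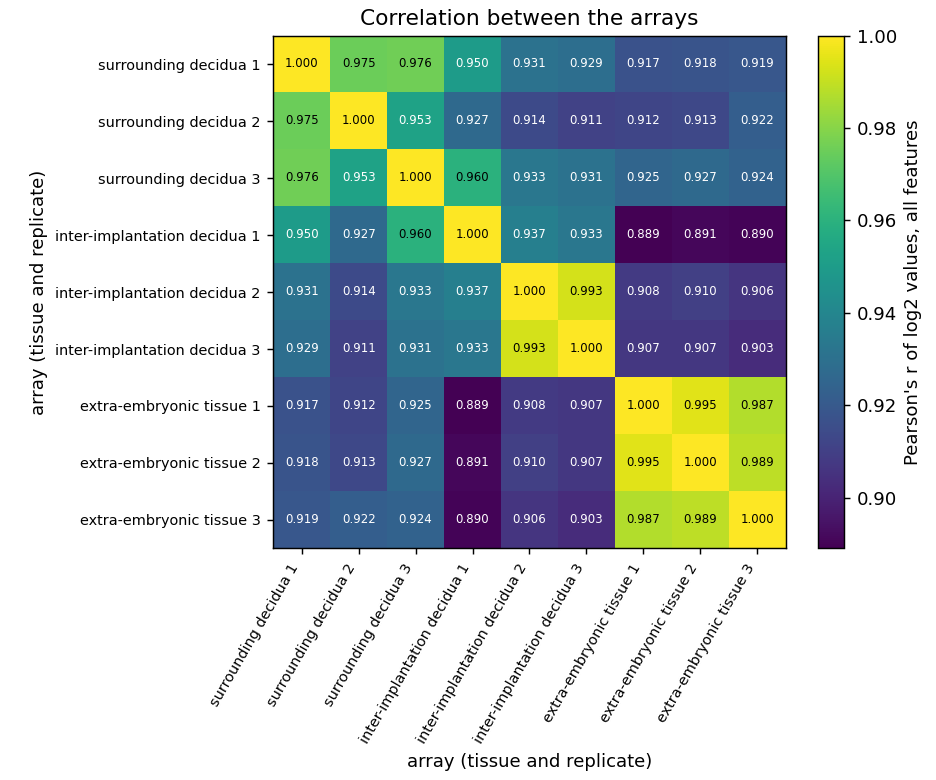
Pearson's r of the log2 values over all features for each pair of arrays, with tissue and replicate on both axes and colour giving r. Extra-embryonic replicates 1 and 2 (0.995) and inter-implantation replicates 2 and 3 (0.993) are the closest pairs, and inter-implantation replicate 1 lies nearer to surrounding decidua replicates 3 (0.960) and 1 (0.950) than to its own group (0.937 and 0.933).

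The comparison of surrounding with inter-implantation decidua sets decidua dissected from a site with an embryo against a segment of uterine wall between sites. The muscle list had median levels of 6.47 to 6.85 in surrounding decidua and 8.11 to 9.25 in inter-implantation decidua. What was dissected therefore cannot be told apart from an effect of the embryo on the wall. In surrounding decidua 4 genes fell and 0 rose. Mfap4, a microfibril-associated protein of the extracellular matrix, was at least 37-fold lower, at 5.90 ± 0.35 (SD, n = 3) against 11.51 ± 0.42 (SD, n = 2), with an adjusted p of 0.0299. Prss29, a serine protease of the uterine glands, was 36.4-fold lower, at 9.54 ± 0.46 against 14.73 ± 0.30 (adjusted p = 0.0299). The receptor gene Gpr153 was at least 7.09-fold lower (adjusted p = 0.0299) and Tprg at least 2.78-fold lower (adjusted p = 0.0424). At an unadjusted p under 0.05 limma gave 1520 genes higher and 1382 lower. With all 9 arrays as separate samples, as first designed, 277 genes were higher and 442 lower, and with the mouse number as a block as well 88 were higher and 134 lower.

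This count depended on more samples than inter-implantation replicate 1. Without it 338 genes were higher and 726 lower in surrounding decidua, and without replicates 2 and 3 the figures were 139 and 197. In both fits the lone sample left is assumed to vary like the other tissues. Without surrounding decidua replicate 1 or replicate 2, limma called 0 genes, and without replicate 3 it called 3. Of Mfap4, Prss29, Gpr153 and Tprg, 0 stayed called in those first fits, 2 without surrounding decidua replicate 3, and all 4 without either inter-implantation sample. With only the samples of both tissues in the fit 0 genes were called, and at an adjusted p below 0.01 the count was 0 as well.

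Decidual genes set inter-implantation replicate 1 apart from replicates 2 and 3. Prl8a2, a prolactin-family hormone made by decidual cells, was saturated on all surrounding decidua arrays and in inter-implantation replicate 1, against 12.43 and 12.51 in replicates 2 and 3. Bmp2, a growth factor that decidualization requires, read 13.35 ± 1.45 (SD, n = 3) in surrounding decidua, 14.09 in inter-implantation replicate 1, and 7.97 and 8.24 in replicates 2 and 3. Wnt4 read 11.18 ± 0.50 in surrounding decidua against 10.86, 6.26 and 6.41 in inter-implantation replicates 1, 2 and 3, and the transcription factor Hand2 read 14.19 ± 0.19 against 13.37, 8.77 and 8.77. None of these 4 genes passed the test (adjusted p from 0.388 to 0.656). Of the 23 measured decidualization genes 22 had a positive difference, with a median log2 difference of 1.59. The median level of the list was 11.86 to 12.21 on the surrounding decidua arrays, 12.10 in inter-implantation replicate 1, and 9.29 and 9.35 in replicates 2 and 3. It lay higher by camera (adjusted p = 0.000305, and adjusted p = 0.592 with an estimated correlation). Of its members 0 were called, also 0 adjusted over the list alone.

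The lists of muscle and uterine epithelium had mostly negative differences. The myometrial smooth muscle list had 17 of 18 members with a negative difference and a median of -1.65 (camera adjusted p = 2.86e-11, and adjusted p = 0.403 with an estimated correlation). Over all genes 0 members were called, and adjusted over the list alone 11 were lower and 1 higher. Cnn1, a calponin of smooth muscle, read 6.35 ± 0.45 in surrounding decidua (SD, n = 3) against 14.30 ± 1.14 (SD, n = 2), with an adjusted p of 0.0511 that became 0.00128 with all 9 arrays. Smooth muscle actin Acta2 read 9.90 ± 0.92 against 14.53 ± 1.44 (adjusted p = 0.177), and smooth muscle myosin Myh11 read 6.44 ± 0.57 against 9.56 ± 1.69 (adjusted p = 0.198). The uterine epithelium list had a median of -1.18, with 1 of 22 members called, the protease Prss29, and 4 lower adjusted over the list alone (camera adjusted p = 2.16e-05, and adjusted p = 0.403 with an estimated correlation). Epithelial cadherin Cdh1 read 7.71 ± 0.30 against 10.28 ± 2.07 (adjusted p = 0.311). Inter-implantation replicate 1 stood apart in both lists. The epithelium list had a median level of 8.55 there, against 11.33 and 11.36 in replicates 2 and 3 and 6.61 to 8.21 in surrounding decidua, and Cdh1 read 8.82 against 11.81 and 11.68. The muscle list had a median level of 8.11 there, against 9.12 and 9.25, and 6.47 to 6.85 in surrounding decidua.

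The fit of all 9 arrays names further genes, none of which was called with 7 samples. Its largest falls by measured difference in surrounding decidua were Cnn1, Pcp4, Klk1b5, Ccl21a, Egfbp2 and Napsa. Klk1b5 and Egfbp2 are kallikrein-family proteases and Ccl21a is a chemokine. Their measured log2 differences with 7 samples ran from -7.95 for Cnn1 to -5.92 for Napsa, with adjusted p from 0.0511 to 0.179. Its largest rises by measured difference were the placental lactogen gene Prl3d2, the protease inhibitor A2m, Prl8a9, the metallothionein Mt4, Serpinb9f and the collagenase Mmp1a. With 7 samples these had measured log2 differences from 6.42 ± 1.66 (SE) for Prl3d2 to 3.56 ± 1.01 for Mt4, with adjusted p from 0.189 to 0.250. In extra-embryonic tissue Prl3d2, Serpinb9f, Prl8a9 and Mmp1a had means of 15.74, 12.31, 11.41 and 11.33, and A2m and Mt4 of 8.45 and 7.98.

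Further lists shifted in this comparison by camera without any member called over all genes. The placental prolactin family lay higher in all 14 members (median 1.71, adjusted p = 0.000742, and adjusted p = 0.458 with an estimated correlation), with 0 adjusted over the list alone. Its median level was 8.31, 8.78 and 5.88 in surrounding decidua replicates 1, 2 and 3, and 5.74 to 5.77 in inter-implantation decidua. The list of the ectoplacental cone and giant cells, which did not pass (adjusted p = 0.103), had median levels of 9.07, 9.84 and 6.73 in these replicates and 6.25 to 6.93 in inter-implantation decidua. Macrophage and antigen-presenting cell genes lay lower in 17 of 19 (median -1.32, adjusted p = 4.86e-06, and adjusted p = 0.458 with an estimated correlation), with 6 lower adjusted over the list alone. Their median level was 8.62 in inter-implantation replicate 1, 10.23 and 10.31 in replicates 2 and 3, and 7.79 to 8.21 in surrounding decidua. Uterine fibroblast genes had a median of -2.05 (adjusted p = 0.00615, and adjusted p = 0.443 with an estimated correlation), and red blood cell genes one of -1.63 (adjusted p = 0.000604, and adjusted p = 0.443 with an estimated correlation). The red blood cell median was 6.63 in inter-implantation replicate 1, within the 6.23 to 6.64 of surrounding decidua, against 9.02 and 9.13 in replicates 2 and 3. The fibroblast median was 8.38 in surrounding decidua replicate 2, against 11.31 and 11.50 in replicates 1 and 3. Chemokines had a median of -0.68 (adjusted p = 3.91e-05, and adjusted p = 0.403 with an estimated correlation), and collagens and basement membrane one of -0.86 (adjusted p = 0.0099, and adjusted p = 0.648 with an estimated correlation). Adjusted over the list alone, 1, 3, 4 and 0 of the members of these 4 lists were lower. The collagen list had median levels of 10.57, 9.46 and 11.31 in surrounding decidua replicates 1, 2 and 3. In inter-implantation replicates 1, 2 and 3 they were 11.26, 10.56 and 10.54, so only surrounding decidua replicate 2 lay below all of these. Mast cell, mesothelium and BMP and TGF-beta lists did not pass (adjusted p = 0.0516, 0.112 and 0.131), with adjusted p = 0.532, 0.592 and 0.592 with an estimated correlation. With all 9 arrays as separate samples the adjusted p was 0.0251, 0.0337 and 0.0633, and with the mouse number as a block as well it was 0.0228, 0.026 and 0.0248. Natural killer genes did not pass (median -0.09, mean 0.11, camera direction down, adjusted p = 0.394), and their receptor gene Ncr1 read 6.63 ± 0.97 (SD, n = 3) against 6.11 ± 0.21 (SD, n = 2). Endothelial genes did not pass either (median 0.02, adjusted p = 0.891), with Pecam1 at 9.28 ± 0.61 against 7.81 ± 1.05. Vegfa read 10.29 ± 0.84 against 8.76 ± 0.45 (adjusted p = 0.340), and its receptor gene Flt1 10.16 ± 0.81 against 9.69 ± 2.04 (adjusted p = 0.874).

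**Figure D2:**
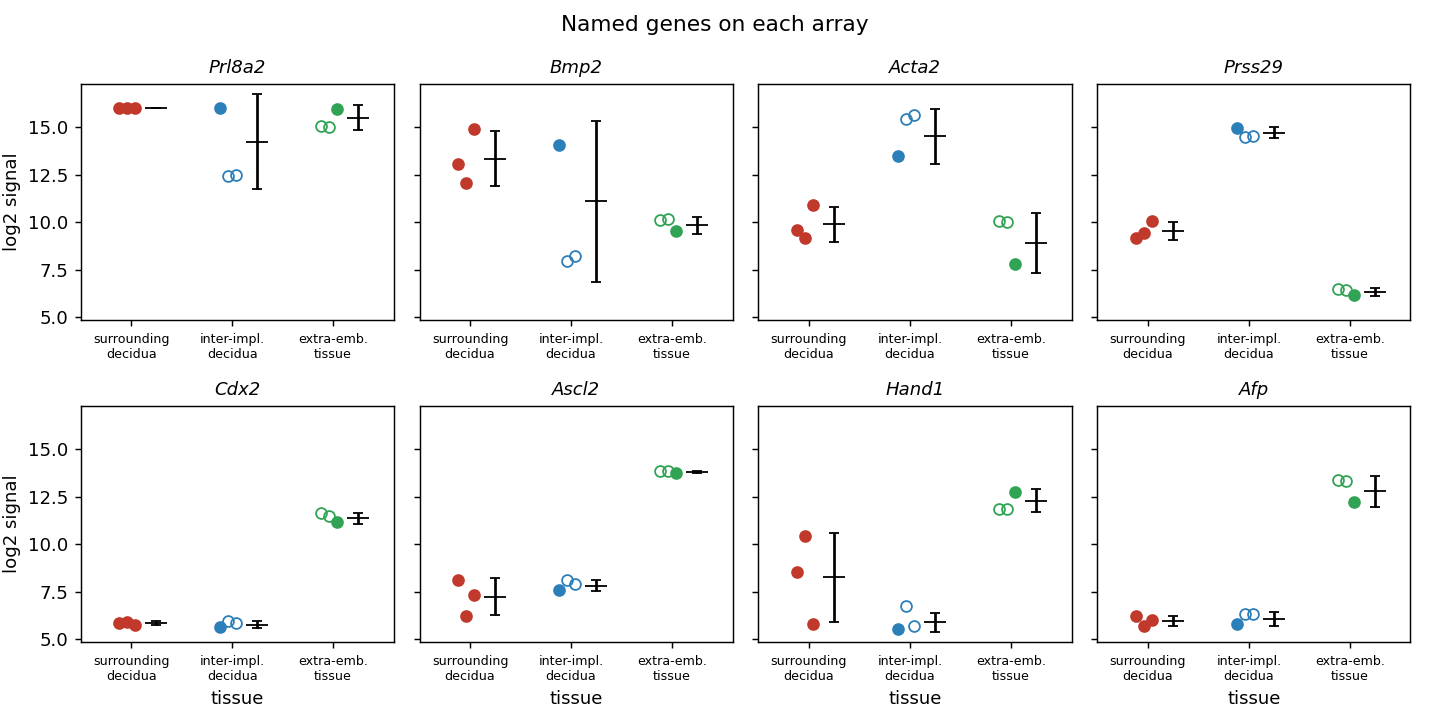
Log2 signal (vertical axis) of 8 named genes on each array, by tissue (horizontal axis). Each circle is 1 array, open circles are the near-identical pairs counted as 1 sample, and the black bar gives the mean ± SD over samples. Bmp2 in inter-implantation replicate 1 (14.09) lies in the range of surrounding decidua, while Prss29 (14.94) lies with the other inter-implantation arrays.

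The comparison of extra-embryonic tissue with surrounding decidua sets the embryonic side of the implantation site against the maternal side. In extra-embryonic tissue 1065 genes rose and 785 fell, and with all 9 arrays as separate samples 1767 were higher and 1474 lower, or 1585 and 1310 with the mouse number as a block as well. The apolipoprotein gene Apoc2 was 274-fold higher, at 14.87 ± 0.97 (SD, n = 2) against 6.78 ± 0.22 (SD, n = 3), with an adjusted p of 0.00162. The sulfate transporter gene Slc13a4 was at least 174-fold higher (adjusted p = 0.00148) and alpha-fetoprotein Afp at least 90.1-fold (adjusted p = 0.00169). Apom was at least 92.9-fold, Bex1 at least 111-fold and Bex4 at least 107-fold higher.

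Visceral endoderm is the yolk sac layer that takes up and secretes nutrients. Of 15 visceral and parietal endoderm genes 13 rose and 0 fell, and 14 were higher adjusted over the list alone. Their median log2 difference was 4.68 (camera adjusted p = 5.44e-14, and adjusted p = 0.403 with an estimated correlation). Amn, part of an endocytic receptor, was at least 77-fold higher. Of 11 epiblast genes 6 rose, also 6 adjusted over the list alone (median 2.33, adjusted p = 3.8e-06, and adjusted p = 0.403 with an estimated correlation). The homeobox gene Otx2 was at least 19.8-fold higher and the DNA methyltransferase Dnmt3b 27.9-fold higher. The labels name the ectoplacental cone as the extra-embryonic tissue, while the genes of these lists are known from other embryonic layers.

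Some trophoblast genes rose as well. Of 13 genes of trophoblast stem cells and extra-embryonic ectoderm 4 rose and 0 fell, also 4 adjusted over the list alone (median 1.42, adjusted p = 7.5e-05, and adjusted p = 0.403 with an estimated correlation). Cdx2 was at least 34-fold higher, at 11.38 ± 0.29 (SD, n = 2) against 5.86 ± 0.09 (SD, n = 3), and Elf5 at least 17.8-fold, both with an adjusted p of 0.00133. Of 15 genes of the ectoplacental cone and giant cells 4 rose, and 5 were higher adjusted over the list alone (median 2.13, adjusted p = 0.000124, and adjusted p = 0.403 with an estimated correlation). Ascl2, a transcription factor of the ectoplacental cone, was at least 94.3-fold higher (adjusted p = 0.00427) and the imprinted gene Phlda2 40.3-fold (adjusted p = 0.0202). Tpbpa, a marker of spongiotrophoblast, was dim in all 3 tissues, at 5.72 ± 0.03 against 5.65 ± 0.18. Hand1 did not pass (12.30 ± 0.62 against 8.26 ± 2.34, adjusted p = 0.117), and read 8.54, 10.46 and 5.79 in surrounding decidua replicates 1, 2 and 3, as the list of the ectoplacental cone and giant cells had medians of 9.07, 9.84 and 6.73 there. The placental prolactin list did not pass (median 0.11, adjusted p = 0.957), and 0 of its 14 members were called, nor any adjusted over the list alone.

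Imprinted and dividing-cell genes were among the rises. Of 13 genes expressed from the paternal allele 6 rose, and 7 were higher adjusted over the list alone (median 1.42, adjusted p = 0.000253, and adjusted p = 0.403 with an estimated correlation). Dlk1 was 9.72-fold higher (adjusted p = 0.0269) and Igf2, a fetal growth factor, at least 2.24-fold (adjusted p = 0.00412). Of 12 genes expressed from the maternal allele 4 rose and 2 fell, with 6 higher and 3 lower adjusted over the list alone (adjusted p = 0.290), and H19 read 11.29 ± 0.09 (SD, n = 2) against 9.43 ± 1.38 (SD, n = 3), with an adjusted p of 0.209. Of 23 cell cycle genes 6 rose, and 12 were higher adjusted over the list alone (median 1.91, adjusted p = 7.38e-07, and adjusted p = 0.532 with an estimated correlation). Cyclin E1, Ccne1, was 5.13-fold higher and the replication helicase subunit Mcm7 4.71-fold higher. Of 19 hypoxia and glycolysis genes 3 rose, with 6 higher adjusted over the list alone (median 1.16, adjusted p = 0.0286, and adjusted p = 0.443 with an estimated correlation), among them Pfkl at 6.57-fold and Ldha at 3.00-fold, both glycolytic enzymes. Red blood cell genes had a median of 2.29, with 2 of 8 called and 4 higher adjusted over the list alone (adjusted p = 0.00137, and adjusted p = 0.443 with an estimated correlation). The adult globin gene Hba-a1 was at least 7.56-fold higher and the heme enzyme Alas2 6.21-fold. The median level of the red blood cell list was 10.19, 10.17 and 8.14 in extra-embryonic replicates 1, 2 and 3, and 6.23 to 6.64 in surrounding decidua. Replicate 3 thus lay well below replicates 1 and 2, though above surrounding decidua.

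The matrix gene Mgp was at least 115-fold lower in extra-embryonic tissue, at 8.59 ± 0.78 (SD, n = 2) against 15.43 ± 0.43 (SD, n = 3), with an adjusted p of 0.00235. The chemokine Cxcl14 was 78.6-fold lower (adjusted p = 0.0171), the thyroid hormone-inactivating enzyme Dio3 73.2-fold (adjusted p = 0.0448), the microfibril gene Mfap5 at least 73.1-fold (adjusted p = 0.00786), the Wnt antagonist Sfrp4 47.5-fold (adjusted p = 0.0147) and the tachykinin gene Tac2 46.9-fold (adjusted p = 0.0384). Of 23 decidualization genes 6 fell and 0 rose, and 14 were lower adjusted over the list alone (median -2.48, adjusted p = 5.36e-08, and adjusted p = 0.532 with an estimated correlation). Hoxa11 was 23-fold lower and the chaperone Cryab 14.1-fold. Wnt4 (adjusted p = 0.103), Hand2 (adjusted p = 0.0843) and Bmp2 (adjusted p = 0.298) did not pass. Of 18 muscle genes 1 fell, Des, a filament protein also made by decidual cells, which was 35.7-fold lower, while the list did not pass (adjusted p = 0.0671). Acta2 read 8.92 ± 1.59 against 9.90 ± 0.92.

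Some vessel and immune lists lay lower in extra-embryonic tissue by camera, while T and B cells, mast cells, chemokines and angiogenic factors did not pass (adjusted p = 0.891, 0.57, 0.184 and 0.0678). By fry the endothelial, macrophage, interferon and natural killer lists did not pass (adjusted p = 0.0895, 0.115, 0.168 and 0.341). Angiogenic factors did pass by fry (adjusted p = 0.0288), so which of these lists passed depended on the test. Of 18 endothelial genes 6 fell, and 9 were lower adjusted over the list alone (median -1.21, adjusted p = 2.6e-05, and adjusted p = 0.532 with an estimated correlation). Emcn was at least 10.7-fold and Mmrn2 8.22-fold lower, while Pecam1 read 9.06 ± 1.02 (SD, n = 2) against 9.28 ± 0.61 (SD, n = 3). Of 19 macrophage and antigen-presenting genes 2 fell, the complement gene C1qc at least 4.38-fold and the MHC class II gene H2-Eb1 3.62-fold, and 3 were lower adjusted over the list alone (median -1.41, adjusted p = 1.5e-05, and adjusted p = 0.498 with an estimated correlation). Of 17 interferon response genes 2 fell, also 2 adjusted over the list alone (median -1.41, adjusted p = 0.000124, and adjusted p = 0.577 with an estimated correlation), with Irf7 5.51-fold lower. Natural killer genes had a median of -1.03 with 0 of 19 called, also 0 adjusted over the list alone (adjusted p = 0.0102, and adjusted p = 0.644 with an estimated correlation). Their median level was 9.85, 7.37 and 8.5 in surrounding decidua replicates 1, 2 and 3, and 6.91 to 7.41 in extra-embryonic tissue. Surrounding decidua replicate 2 thus lay within the extra-embryonic range. Of 20 extracellular proteases and inhibitors 4 fell and 1 rose, with 5 lower and 1 higher adjusted over the list alone (median -0.57, adjusted p = 0.00886, and adjusted p = 0.403 with an estimated correlation). The matrix metalloproteinase Mmp9 was 7.12-fold higher and the inhibitor Timp2 9.96-fold lower. Of 11 uterine fibroblast genes 1 fell, Mfap5, also 1 adjusted over the list alone (median -1.80, adjusted p = 0.00546, and adjusted p = 0.443 with an estimated correlation). The median level of this list was 11.31, 8.38 and 11.5 in surrounding decidua replicates 1, 2 and 3. In extra-embryonic tissue it was 7.75 to 8.39, so surrounding decidua replicate 2 lay within that range. The steroid hormone list did not pass (adjusted p = 0.875), with a median of -0.18 and a mean of 0.34, nor did the placental cathepsins (median -0.04, mean 0.51, adjusted p = 0.891).

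Single samples carried these calls to different degrees. The count of 1850 genes was 496 without surrounding decidua replicate 1, 175 without extra-embryonic replicates 1 and 2, and 291 without extra-embryonic replicate 3. In the last 2 fits the lone extra-embryonic sample left is assumed to vary like the other tissues. Of the 71 called genes that the naming rule gave, 17 stayed called whichever sample of these tissues was left out, among them Apoc2, Slc13a4, Bex4, Afp, Apom, Mgp, Des, Cdx2, Elf5, Otx2, Dnmt3b, Amn and Igf2. Of the 71, 28, 47 and 56 stayed called without surrounding decidua replicates 1, 2 and 3, 18 without extra-embryonic replicates 1 and 2, and 23 without extra-embryonic replicate 3. None of the 71 turned direction in these fits. The fit of all 9 arrays also named the embryonic globin Hbb-bh1 and the Wnt antagonist Sfrp5, which were not called with 7 samples (adjusted p = 0.205 and 0.078), and the receptor Trem2, which fell 44.4-fold.

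**Figure D3:**
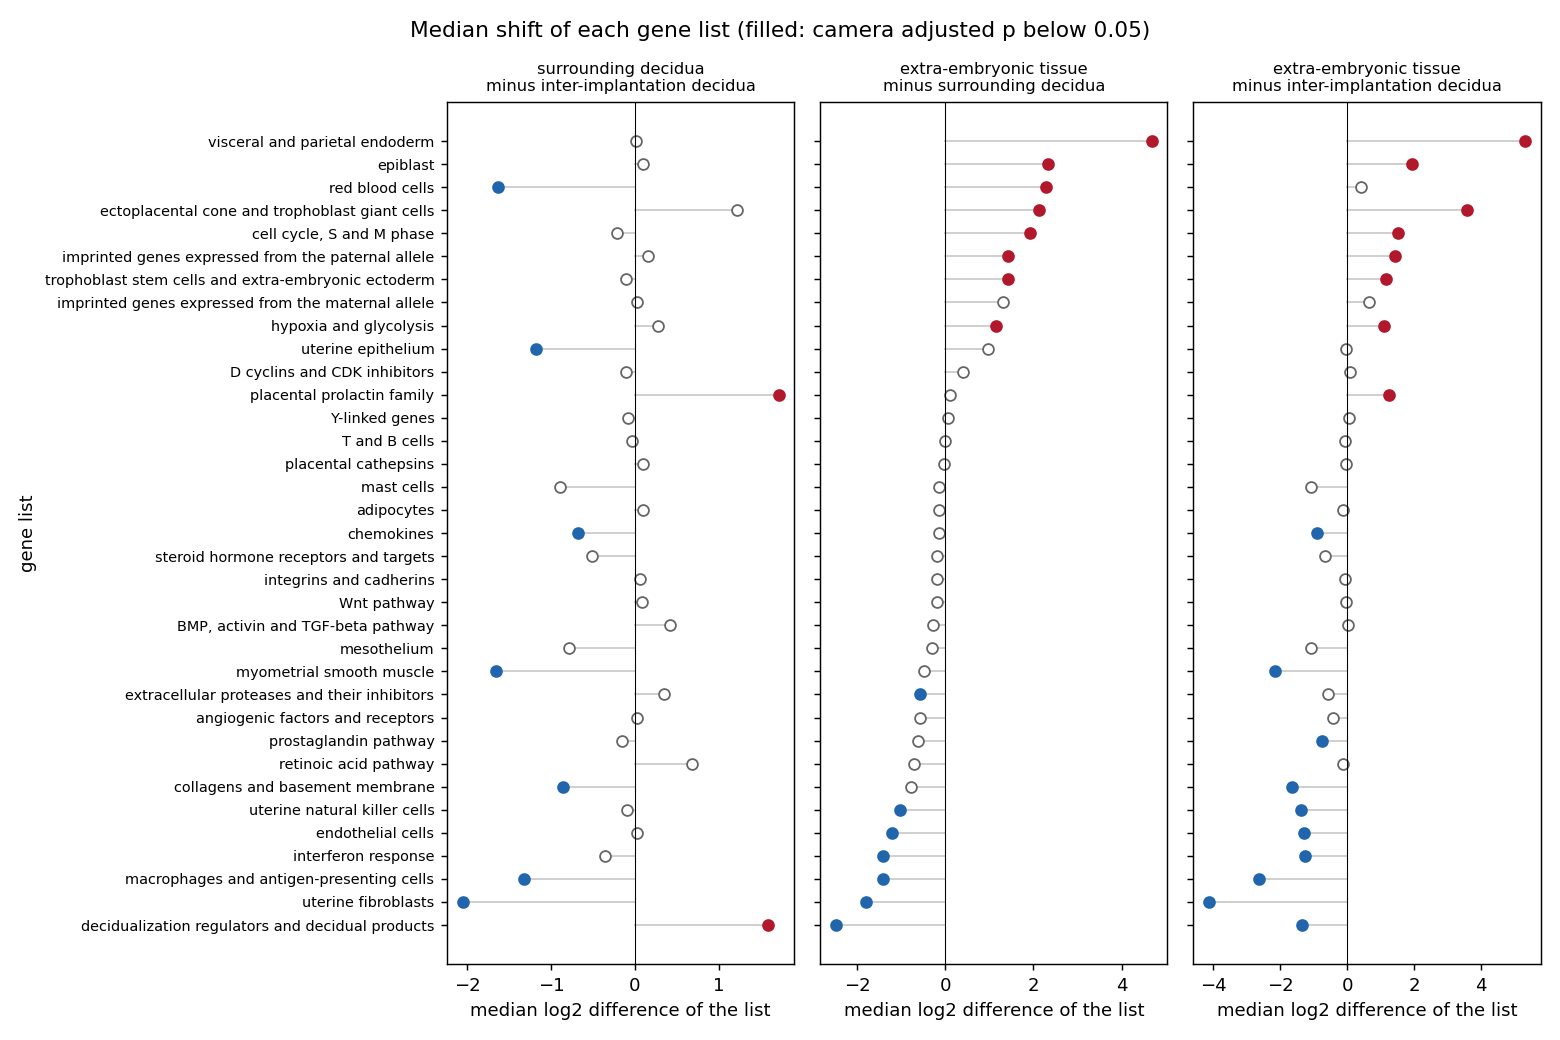
Median log2 difference (horizontal axis) of each of 35 gene lists (vertical axis) in the 3 comparisons, each panel with its own scale, filled where camera's adjusted p with the preset correlation was below 0.05 (red higher, blue lower) and open otherwise. Visceral and parietal endoderm has the largest positive median against both uterine tissues (4.68 against surrounding decidua).

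The comparison of extra-embryonic tissue with inter-implantation decidua sets the embryonic side against uterine wall away from the embryo. In extra-embryonic tissue 1154 genes rose and 755 fell, and with all 9 arrays as separate samples 1961 were higher and 1613 lower, or 1808 and 1477 with the mouse number as a block as well. Without inter-implantation replicate 1 the balance turned, with 849 genes higher and 1098 lower. Prl3d2, which encodes a placental lactogen of giant cells, was at least 404-fold higher, at 15.74 ± 0.34 (SD, n = 2) against 6.97 ± 1.26 (SD, n = 2), with an adjusted p of 0.0401. The homeobox gene Rhox5 was saturated in extra-embryonic tissue and at least 296-fold higher (adjusted p = 0.0302). Slc13a4 was at least 163-fold, Apoc2 190-fold, Cited1 164-fold and Phlda2 at least 161-fold higher.

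The embryonic lists that rose against surrounding decidua also held called genes here. Of 15 visceral and parietal endoderm genes 14 rose, also 14 adjusted over the list alone (mean log2 difference 4.65, adjusted p = 1.2e-13, and adjusted p = 0.403 with an estimated correlation), with Afp at least 88.6-fold higher. Of 15 ectoplacental cone and giant cell genes 7 rose, and 9 were higher adjusted over the list alone (median 3.57, adjusted p = 7.9e-06, and adjusted p = 0.403 with an estimated correlation). Hand1, a regulator of giant cell formation, was at least 63.9-fold higher (adjusted p = 0.0474) and Ascl2 64.1-fold (adjusted p = 0.00807). Of 13 trophoblast stem cell genes 4 rose, and 5 were higher adjusted over the list alone (median 1.17, adjusted p = 0.000466, and adjusted p = 0.403 with an estimated correlation), with Cdx2 at least 33.8-fold and Elf5 at least 17.7-fold higher. Of 11 epiblast genes 5 rose, and 6 were higher adjusted over the list alone (median 1.94, adjusted p = 5.2e-05, and adjusted p = 0.403 with an estimated correlation), with Dnmt3b 33.5-fold higher. Prolactin family genes had a median of 1.26 with 0 of 14 called and 4 higher adjusted over the list alone (adjusted p = 0.0284, and adjusted p = 0.592 with an estimated correlation). Their median level was 6.64, 6.67 and 8.89 in extra-embryonic replicates 1, 2 and 3, and 5.74 to 5.77 in inter-implantation decidua, so replicate 3 stood apart. Of 13 paternally expressed genes 5 rose, and 7 were higher adjusted over the list alone (adjusted p = 6.46e-05, and adjusted p = 0.403 with an estimated correlation). Igf2 was at least 2.23-fold higher (adjusted p = 0.00496), and H19 did not pass (adjusted p = 0.0502).

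Among other genes, the gelatinase Mmp9 was at least 25.5-fold higher in extra-embryonic tissue (adjusted p = 0.0123), and the inhibitors Timp1 and Timp2 were 12.5-fold (adjusted p = 0.0394) and 10.2-fold lower (adjusted p = 0.00411). The list of proteases and inhibitors did not pass as a whole (adjusted p = 0.0962), with 1 member higher and 3 lower, and 1 higher and 5 lower adjusted over the list alone. The retinol carrier Rbp4 was 39.3-fold and the cell cycle inhibitor Cdkn1c 24.2-fold higher. Ccne1 was 8.39-fold higher, 1 of 23 cell cycle genes called over all genes and 6 adjusted over the list alone (median 1.51, adjusted p = 7.9e-06, and adjusted p = 0.557 with an estimated correlation). Of 19 hypoxia and glycolysis genes 4 rose, and 8 were higher adjusted over the list alone (adjusted p = 0.00631, and adjusted p = 0.403 with an estimated correlation).

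Prss28, a serine protease of the uterine glands, was at least 370-fold lower, at 7.06 ± 0.50 (SD, n = 2) against 15.59 ± 0.47 (SD, n = 2), with an adjusted p of 0.00366, and Prss29 was at least 325-fold lower (adjusted p = 0.00246). The uroguanylin gene Guca2b was at least 170-fold (adjusted p = 0.0317), the aspartic protease Napsa 102-fold (adjusted p = 0.0324) and the surfactant protein Sftpd at least 93.3-fold lower (adjusted p = 0.0201). Of 22 uterine epithelium genes 5 fell and 2 rose, with 6 lower and 3 higher adjusted over the list alone, and the list did not pass (adjusted p = 0.187). The 2 that rose, Ihh and Foxa2, are also genes of the embryonic endoderm. Of 18 muscle genes 9 fell, and 11 were lower adjusted over the list alone (median -2.15, adjusted p = 1.93e-10, and adjusted p = 0.403 with an estimated correlation). Actin gene Actg2 was 173-fold, Cnn1 89.2-fold, Acta2 49-fold and Myh11 at least 9.61-fold lower.

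Members of stromal and immune lists fell too. Of 11 uterine fibroblast genes 4 fell, and 9 were lower adjusted over the list alone (median -4.12, adjusted p = 1.5e-05, and adjusted p = 0.403 with an estimated correlation), with decorin Dcn 92.3-fold lower. Of 19 macrophage and antigen-presenting genes 8 fell, and 13 were lower adjusted over the list alone (median -2.63, adjusted p = 1.71e-09, and adjusted p = 0.403 with an estimated correlation), with C1qc at least 17-fold and C1qa at least 13.4-fold lower. Of 23 chemokines 5 fell, and 9 were lower adjusted over the list alone (median -0.89, adjusted p = 1.19e-05, and adjusted p = 0.403 with an estimated correlation), with Ccl21a 77.9-fold lower (adjusted p = 0.0495). Collagen genes had 2 of 21 called, the collagen VI chains Col6a1 (50.7-fold lower) and Col6a2 (at least 8.73-fold), and 10 lower and 2 higher adjusted over the list alone (adjusted p = 0.00406, and adjusted p = 0.602 with an estimated correlation). The estrogen receptor Esr1 was at least 11.3-fold lower (adjusted p = 0.019). Of 23 decidualization genes 1 fell, Stat3 (5.16-fold), and 5 were lower adjusted over the list alone (median -1.35, adjusted p = 0.00195, and adjusted p = 0.648 with an estimated correlation). The median level of this list was 12.10 in inter-implantation replicate 1, 9.29 and 9.35 in replicates 2 and 3, and 9.45 to 9.52 in extra-embryonic tissue. By these medians the lower level of the list rested on inter-implantation replicate 1.

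Of 18 endothelial genes 6 fell, with Mmrn2 12.6-fold lower, and 9 were lower adjusted over the list alone (median -1.28, adjusted p = 0.000127, and adjusted p = 0.532 with an estimated correlation). Of 17 interferon response genes 2 fell, Gbp2 at least 9.85-fold and the transcription factor Irf1 2.12-fold, and 3 were lower adjusted over the list alone (median -1.25, adjusted p = 2.97e-05, and adjusted p = 0.532 with an estimated correlation). Of 10 prostaglandin genes 1 fell, the phospholipase Pla2g4a, also 1 adjusted over the list alone (median -0.76, adjusted p = 0.0296, and adjusted p = 0.443 with an estimated correlation). Natural killer genes had a median of -1.38 with 0 of 19 called, also 0 adjusted over the list alone (adjusted p = 0.00383, and adjusted p = 0.592 with an estimated correlation). Their median level was 9.69 in inter-implantation replicate 1, 6.88 and 6.75 in replicates 2 and 3, and 6.91 to 7.41 in extra-embryonic tissue. By these medians the lower level rested on inter-implantation replicate 1. Red blood cell genes did not pass (median 0.42, adjusted p = 0.466). The retinoic acid list (median -0.12, mean 0.23, adjusted p = 0.655) and the BMP and TGF-beta list (median 0.03, mean -0.18, adjusted p = 0.729) did not pass either. The mast cell list did not pass (adjusted p = 0.0513, and adjusted p = 0.532 with an estimated correlation). With all 9 arrays as separate samples its adjusted p was 0.0174, and 0.0134 with the mouse number as a block as well.

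Of the 1909 genes 1184 were also called without inter-implantation replicate 1, where 849 genes were higher and 1098 lower. The count was 3033 without inter-implantation replicates 2 and 3, 170 without extra-embryonic replicates 1 and 2, and 220 without extra-embryonic replicate 3. In each of these 4 fits the lone sample left of a tissue is assumed to vary like the other tissues. With only the samples of both tissues in the fit it was 720. Of 70 called genes that the naming rule gave, 16 stayed called whichever sample of these tissues was left out, among them Slc13a4, Apoc2, Prss28, Prss29, Actg2, Cdx2, Elf5, Dnmt3b, Otx2, Afp and Timp2. Of the 70, 48 stayed called without inter-implantation replicate 1, 56 without inter-implantation replicates 2 and 3, 18 without extra-embryonic replicates 1 and 2, and 19 without extra-embryonic replicate 3. The fit of all 9 arrays also named Prl4a1 and Plac1, which were not called with 7 samples (adjusted p = 0.0808 and 0.0531).

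In extra-embryonic tissue 740 genes were higher than in both uterine tissues, against 54.7 for independent lists and 0 in 20 simulated sets of unchanged groups that shared the arrays. Both comparisons use the same extra-embryonic samples, and part of the excess may come from them. The simulated sets held no changed genes, so hardly any gene could be called in either comparison. Their 0 is therefore no chance level for the 740, nor for the inter-implantation genes below. With all 9 arrays the count was 1203, and without extra-embryonic replicates 1 and 2 it was 111, without extra-embryonic replicate 3 it was 163 and without surrounding decidua replicate 1 it was 267. A lone extra-embryonic or inter-implantation sample left in a fit is again assumed to vary like the other tissues. The 5 that the naming rule gave were Apoc2, with a smaller log2 difference of 7.57, and Slc13a4, Afp, Apom and Bex4, whose differences are bounds, so that the order of the 5 is not known. In inter-implantation decidua 4 genes were higher than in both others, against 0.134 for independent lists and 0 in the simulated sets. They were Prss29, Mfap4, Gpr153 and Tprg. With all 9 arrays the count was 320, and 108 with the mouse number as a block as well, while leaving out a surrounding decidua or extra-embryonic sample brought it to 0 to 2, and leaving out inter-implantation replicate 1 brought it to 529 and replicates 2 and 3 to 173. In surrounding decidua limma called 0 genes higher than in both others, 594 at an unadjusted p under 0.05 in both comparisons, and 149 with all 9 arrays.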

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

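The design fixed beforehand took all 9 arrays as separate samples. Averaging the near-identical pairs to 7 samples, which the reported values use, was decided after the data were examined, and the other settings were planned. Quantile normalization, an equal 75th percentile, leaving out dim genes, the brightest feature, a test per feature and no fold threshold kept the counts of genes called within 1.5 times. They ran from 3 to 4 for surrounding minus inter-implantation decidua, 1832 to 2331 for extra-embryonic tissue minus surrounding decidua and 1879 to 2282 for extra-embryonic tissue minus inter-implantation decidua. In the first of these the genes were not all the same. The brightest feature kept 2 of the 4, and leaving out dim genes and the test per feature each kept 3. Quantile normalization and an equal 75th percentile shifted every array by a median of 0 log2 units, so they could change little. For surrounding minus inter-implantation decidua the count of 4 was 11 with trend and robust variances, 1 with array weights, 0 with only the samples of both tissues, 0 at an adjusted p below 0.01 and 719 with all 9 arrays, and leaving out a sample gave 0 to 1064. For extra-embryonic tissue minus surrounding decidua the count of 1850 was 4051 with array weights, 423 at an adjusted p below 0.01 and 3241 with all 9 arrays, and 175 to 1927 with a sample left out. For extra-embryonic tissue minus inter-implantation decidua the count of 1909 was 720 with only the samples of both tissues, 265 at an adjusted p below 0.01 and 3574 with all 9 arrays, and 170 to 3033 with a sample left out. Genes higher in inter-implantation decidua than in both others numbered 4, 320 with all 9 arrays and 0 to 529 with a sample left out. Those higher in extra-embryonic tissue numbered 740, 1203 with all 9 arrays and 111 to 995 with a sample left out. Of 105 list tests, camera called 42 with its preset correlation and fry called 21, of which 19 were among the 42 with the same direction. In the order of the comparisons above, fry called 2, 8 and 11 lists. Decidualization and cell cycle genes passed fry in no comparison, with lowest adjusted p of 0.104 and 0.084. With an estimated correlation camera called 0, and 1, 5 and 5 lists had an unadjusted p below 0.05. That 0 does not by itself show that correlation undid the shifts of every list. For extra-embryonic tissue minus surrounding decidua, the paternally expressed list had an estimated correlation of -0.05, under the preset 0.01. Its camera adjusted p still went from 0.000253 to 0.403. Estimated correlations ran from -0.10 for the Y-linked list to 0.70 for decidualization genes, with 0.66 for cell cycle and 0.46 for muscle genes. For lists far above the preset 0.01 the preset p-values may be much too low. The part of correlation and that of the few degrees of freedom were not separated. With the mouse number as a block over all 9 arrays, the counts were 222, 2895 and 3285 in the same order, and 108 genes were higher in inter-implantation decidua than in both others. The block over 9 arrays ended no call of a named gene or list. That fit counts the near-identical pairs as separate mice, which itself adds calls, so it cannot show what the pairing does. No block was fitted to the 7 samples. A stricter threshold calls fewer genes by construction. Fitting 9 arrays brings more residual degrees of freedom and, through the near-identical pairs, a smaller spread within a tissue. Leaving out a sample moved counts both ways, and where it left 1 sample of inter-implantation decidua or extra-embryonic tissue, that sample was assumed to vary like the other tissues. Otherwise the cause was not tested. No called gene named here and no called list turned direction in the settings run for it, but the balance of genes called for extra-embryonic tissue minus inter-implantation decidua turned to 849 higher and 1098 lower without inter-implantation replicate 1. A floor on linear values was not run, since the values are log2, nor was leaving out each array of a near-identical pair alone. Levels below the array medians limit what can be said of dim genes.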

Other observations

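The genes in these paragraphs that the report does not name were chosen after their values were seen, and all tests here but that of the share of surrounding decidua were chosen after the result was seen. Embryonic globin differed between arrays of one tissue. Hbb-bh1 read 15.79, 15.79 and 8.59 in extra-embryonic replicates 1, 2 and 3, and 11.44 and 11.61 in inter-implantation replicates 2 and 3, against 6.12 in inter-implantation replicate 1 and 5.94 to 6.81 in surrounding decidua. Eif2s3y, a gene of the Y chromosome, which maternal tissue lacks, rose in extra-embryonic tissue against both others (adjusted p = 0.0309 and 0.0436). It read 7.09, 7.25 and 8.84 there, and was dim elsewhere. It was the 1 called gene among 3 of the Y-linked list, which did not pass (adjusted p = 0.354 and 0.537).

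The granzyme gene Gzme, made by uterine natural killer cells, read 15.16, 9.70 and 12.54 in surrounding decidua replicates 1, 2 and 3, and 15.03, 8.68 and 8.65 in those of inter-implantation decidua. Cyp26a1, an enzyme that breaks down retinoic acid, read 13.06 and 13.30 in inter-implantation replicates 2 and 3, 8.52 in replicate 1, 5.85 to 7.47 in surrounding decidua and 10.16 to 10.43 in extra-embryonic tissue. Timp3, an inhibitor of metalloproteinases, read 14.97 in surrounding decidua replicate 3 and 9.58 to 11.29 on all other arrays.

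Inter-implantation replicate 1 stood apart from replicates 2 and 3. An exchange of labels with surrounding decidua is argued against, as 0 of its arrays lay closer to replicates 2 and 3 than to their own group. Of 100 genes far higher in replicates 2 and 3, 63% lay at least 1 log2 unit above every surrounding decidua array in replicate 1. That argues against surrounding decidua alone under a wrong label. It cannot exclude a mislabelled surrounding decidua sample with some other wall tissue, since the same genes give a surrounding decidua share of 95.1%. A mixture with decidua of an implantation site may account for part of the pattern: 31 genes far higher in surrounding decidua gave a median share of 54.4% (quartiles 34% to 91.4%) and the other 100 gave 95.1% (90.2% to 97.4%), so the quartile ranges just overlap, while the medians lie -40.6 percentage points apart. Such mixing is argued against as the source of 56 genes that lay at least 2 log2 units above every other sample in replicate 1, such as Fgf2 (10.67 against 6.09 or less), since a mixture cannot exceed both its parts and surrounding decidua and extra-embryonic samples had 7 to 15 such genes; the 234 of inter-implantation replicates 2 and 3 were dropped from the comparison after the values were seen, as mixing in replicate 1 would itself raise that count, and with them the test leaves mixing open. No biological explanation was tested.

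Some trophoblast genes, such as Hand1 (8.54, 10.46 and 5.79), were higher in surrounding decidua replicates 1 and 2 than in replicate 3, while others were not, such as Ascl2 (8.15, 6.22 and 7.34) and Cdx2 (5.87, 5.94 and 5.77). Whole extra-embryonic tissue left on the decidua is argued against: from 11 trophoblast genes its share in replicate 2 would be 32.2% (quartiles 13.6% to 98.5%), yet 10 visceral endoderm genes lay at a median of 5.89 where that share predicts 10.34. The median difference was -4.29 (quartiles -5.04 to -3.26), or -3.14 at the lower quartile of the share, and -3.92 in replicate 1. Giant cells that line the implantation chamber and stay on the decidua are a candidate source. The placental prolactin genes were higher in replicate 2 than in replicate 3 by a median of 1.09, but decidual cells express some of these genes too, so the sources cannot be told apart with these samples.

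The number of samples limits what regrouping can show. For surrounding against inter-implantation decidua the real split gave 4 genes and the highest other 1, and 1 of 10 splits gave as many as the real one. For extra-embryonic tissue against surrounding decidua it was 1 of 10, with 1850 genes and 5 in the highest other, and against inter-implantation decidua 1 of 3, with 1909 and 0. With 10 or 3 splits a share under 0.05 cannot be reached.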
